A study of Homo sapiens with 4 samples.

How the data were processed

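Total RNA of HuH7 cells, kept below passage 10, was labelled with biotin for 1-colour whole-transcript arrays, with 1 array per sample. The series holds 2 samples with a control shRNA and 2 with shRNA against MKL1 and MKL2, and groups and replicate numbers were taken from the sample titles. The deposited table gives log2 expression values for 33297 probes in 4 columns, with near-equal quartiles in the 4 columns. The submitters' processing notes name Partek, and the background correction, normalization and summarization are not given in the sources used here. The log2 scale was inferred from the values, which run from 1.03 to 13.65 and on a natural or decimal log scale would exceed a scanner's range. Medians per array lie between 5.68 and 5.73, and genes are not centred. The array of knockdown replicate 1 has a slightly narrower spread than the others, with quartiles of 4.02 and 7.44 against 3.99 and 7.48 in knockdown replicate 2. Scanner files were not used here, so no background level or detection call stands behind a value, and dim genes were not removed.

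Probes were named from the platform annotation. Of the 33297 probes, 19460 list 1 gene symbol, 1754 list several and 12083 are not listed. Symbols were updated through Entrez identifiers, and 19429 of the 19460 were found in the RefSeq gene table of assembly GRCh38.p14, which was used for names alone. Where a gene had more than 1 probe (769 genes), the probe with the highest mean over the 4 arrays was used, which gave 18417 genes. The MRTFA probe lists a second gene, so it was tested beside the 18417 genes and not among them. Older names on the gene lists, such as MKL1 and CTGF, were matched through synonyms.

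Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, group as the only term), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. There are 2 residual degrees of freedom, and eBayes added 4.12 prior degrees of freedom. Errors of levels are SDs over 2 arrays, and errors of differences are limma's moderated standard errors. Log2 differences are knockdown minus control. A total of 18 gene lists were fixed before the data were examined, as were the test, the alternatives and the rule for named genes. Lists were tested with limma's camera at its preset correlation of 0.01 between genes, with adjustment over the 18 lists. Beside it stand camera with an estimated correlation, fry, and counts of members past the threshold over all genes tested and adjusted over the list alone. With an estimated correlation, 0 of the lists passed an adjusted p of 0.05 in camera, and 1, hypoxia and glycolysis, had an unadjusted p under 0.05. The named genes are the shRNA targets, SRF and MYOF, the 12 largest falls and 12 largest rises among genes past the threshold whose groups did not overlap, leaving out uncharacterised loci and small RNAs, and the 4 members with the smallest p in each list. Lists were compared with 10000 random lists matched on mean level, with members drawn within 200 ranks.

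The procedure was tested on simulated data, with 5 sets of 4 arrays drawn for the 18417 genes from the real means and the fitted variances and 200 genes changed. A further 40 genes were raised by 0.4 on the log2 scale in the knockdown arrays as a set, and their recovery as single genes was not counted. On average the procedure called 83.4% of genes changed 2-fold and 99% of those changed 4-fold, and 3.89% of its calls were false. The simulated genes varied independently of each other and with the same variance in both groups. The real knockdown arrays differed more from each other (SD 0.265) than the controls did (SD 0.154), so the rates may not carry over. In the real data 35 genes were lower and 63 higher by at least 2-fold with no overlap between the groups. Of these, 15 and 14 passed the threshold, so the simulated rates cannot be read as the share of real 2-fold changes that was called. Alternatives left out the dimmest 40% of genes, renormalized the values by quantiles or medians, averaged probes, used all probes, changed or removed the variance moderation, changed the threshold, added the replicate number as a block, and left out each array in turn. The replicate numbers were not taken to pair the samples, since the labels do not say that a number marks a shared day or batch, and scan dates were not analysed here. No 2 arrays were duplicates, since at most 174 of 33297 probes had identical values in any pair.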

Results

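HuH7, a human hepatocellular carcinoma cell line, was profiled on 1-colour expression arrays after lentiviral delivery of short hairpin RNAs (shRNAs) and 7 days of puromycin selection. The arrays covered 2 cultures that carried a control shRNA and 2 that carried shRNA against MKL1 and MKL2. These genes, now named MRTFA and MRTFB, encode the myocardin-related transcription factors, which are released from monomeric actin and activate transcription through serum response factor (SRF). The comparison asks which transcripts depend on MKL1 and MKL2 in these cells. Each array gave log2 expression values for 33297 probes, with medians between 5.68 and 5.73, and 18417 genes were tested. The control arrays lay closest together, with an SD of 0.154 over genes for their log2 difference. The knockdown arrays differed from each other by an SD of 0.265, close to the 0.261 to 0.31 between control and knockdown arrays. The titles call the samples biological replicates but do not say whether they came from separate infections. The p-values set the group difference against the spread within the groups, moderated with the spread of all genes. That spread may not cover differences between infections, and the number of samples limits the precision.

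The MKL1 transcript fell by 0.93 on the log2 scale in the knockdown cells, to 0.525 of its control level, whereas the fall of MKL2 did not pass the test. The one probe that lists MRTFA read 7.79 ± 0.023 in control and 6.86 ± 0.066 in knockdown cells (mean ± SD, n = 2 each, limma adjusted p = 0.0404). Its annotation also lists RBM15, but the 4 of its 14 accessions that were found in the RefSeq gene table all belong to MRTFA. The separate RBM15 probe read 7.18 ± 0.074 and 7.09 ± 0.165, with a limma adjusted p of 0.804. MRTFB read 7.21 ± 0.013 in control and 6.98 ± 0.191 in knockdown cells, a log2 difference of -0.23 (SE 0.12, limma adjusted p = 0.448). Adjusted over the targets alone, the p was 0.000124 for the MRTFA probe and 0.103 for MRTFB. The MRTFB value lay 0.36 below the control mean in knockdown replicate 1 and 0.095 below it in replicate 2. SRF itself read 9.89 ± 0.122 in control and 9.45 ± 0.109 in knockdown cells, a log2 difference of -0.44 that did not pass over all genes (SE 0.113, limma adjusted p = 0.188). The call for the MRTFA probe was lost without either control array, at adjusted p = 0.732 without replicate 1 and 0.638 without replicate 2.

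Among the genes that fell in knockdown cells were TAGLN, CNN1, MYH9 and COTL1, which encode actin-binding or motor proteins. Among those that rose were the enzyme genes SULT1E1, ADH1C and AKR1C1 and the genes of the secreted proteins FGL1, HABP2 and C2. In all, 32 genes passed an adjusted p of 0.05 in limma, 17 lower and 15 higher, of which 15 and 14 changed by at least 2-fold. At an unadjusted p under 0.05 in limma there were 1481 lower and 1151 higher genes. Together these were 2632, where chance alone would give about 921 over both directions. The groups did not overlap for 45.5% of genes, against 33.3% by chance with 2 arrays each. The number of calls rests on the arrays used. Without control replicate 1 or control replicate 2 no gene passed in limma (866 and 1219 at an unadjusted p under 0.05), whereas 299 passed without knockdown replicate 1 and 781 without knockdown replicate 2. All 32 genes kept their direction in each of these sets of 3 arrays, as they must, since their groups did not overlap.

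**Figure D1:**
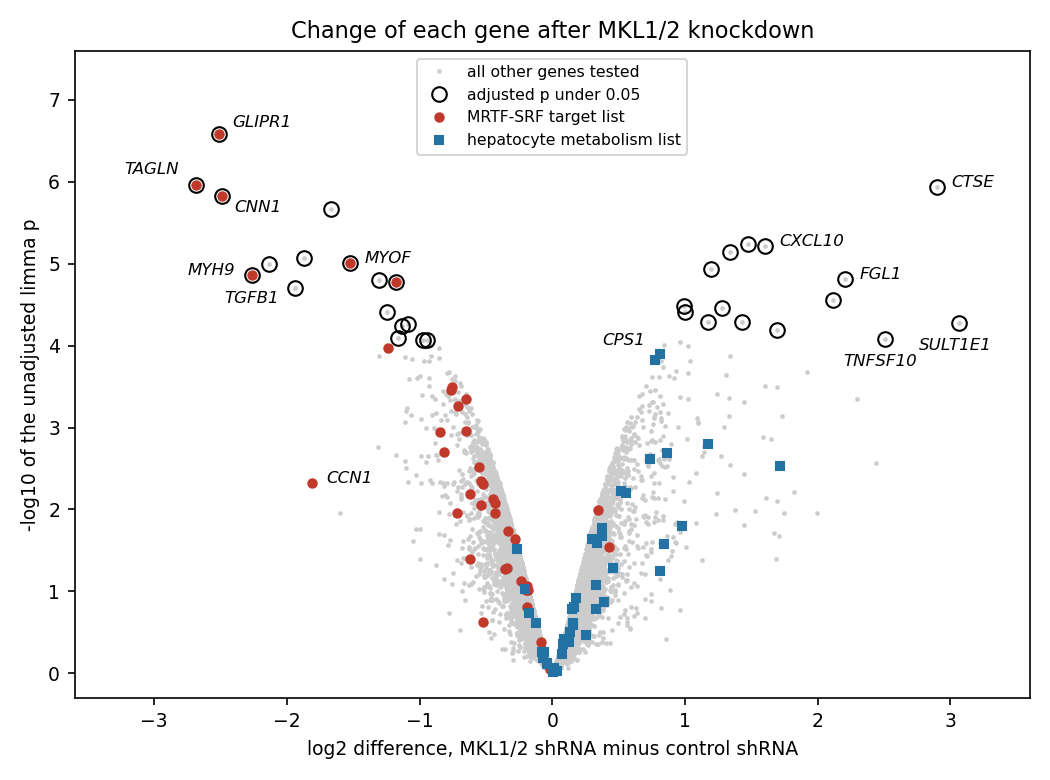
Log2 difference between MKL1/2 shRNA and control shRNA cells (horizontal axis) against -log10 of the unadjusted limma p (vertical axis) for 18417 genes. Open circles mark the 32 genes past an adjusted p of 0.05, red dots the 41 measured MRTF-SRF targets, which lie mostly on the left, and blue squares the 43 measured hepatocyte metabolism genes, which lie mostly on the right.

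TAGLN, GLIPR1, CNN1 and MYH9 had the largest falls among the named genes. TAGLN, which encodes the actin-binding protein transgelin, fell from 8.45 ± 0.062 to 5.77 ± 0.257 (mean log2 value ± SD, n = 2 each), to 0.155 of its control level. CNN1, which encodes calponin, fell from 8.85 ± 0.194 to 6.36 ± 0.16, to 0.178 of control. MYH9, the heavy chain of non-muscle myosin IIA, fell from 10.007 ± 0.052 to 7.75 ± 0.382, to 0.209 of control. GLIPR1, a member of the cysteine-rich secretory protein family, fell from 11.41 ± 0.051 to 8.90 ± 0.108, to 0.176 of control, with the smallest limma adjusted p of all genes (0.00476). The cytokine gene TGFB1 fell by 1.94 (SE 0.165) and VGLL3, a cofactor of TEAD transcription factors, by 1.87 (SE 0.138) on the log2 scale. MYOF, which encodes the membrane protein myoferlin, fell from 8.53 ± 0.126 to 7.005 ± 0.118, to 0.348 of control (limma adjusted p = 0.0167). The microtubule-associated protein gene MAP1B fell by 1.67 (SE 0.098), the LIM domain gene FHL2 by 1.18 (SE 0.098) and the actin-binding COTL1 by 1.17 (SE 0.126). The ganglioside synthase gene B4GALNT1 fell by 1.24 (SE 0.119) and the zinc finger pseudogene ZNF542P by 1.31 (SE 0.107). The other 5 genes that fell were LOC151760, XPR1, GJA1, SOCS2 and PDLIM3, with log2 differences from -2.14 for LOC151760 to -0.95 for PDLIM3; these were named after their values were seen.

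The genes that rose included conjugating enzymes, proteases and a death ligand. SULT1E1, the estrogen sulfotransferase, rose from 4.14 ± 0.26 to 7.21 ± 0.68 (mean log2 value ± SD, n = 2 each). CTSE, the aspartic protease cathepsin E, rose from 7.36 ± 0.193 to 10.26 ± 0.234, a factor of 7.47 (limma adjusted p = 0.00679). TNFSF10, which encodes the death receptor ligand TRAIL, rose 5.68-fold but lay at 8.69 in knockdown replicate 1 and 7.79 in replicate 2, against 5.73 ± 0.04 in the controls (limma adjusted p = 0.0498). FGL1, a fibrinogen-like protein secreted by hepatocytes, rose 4.61-fold, and the protease gene HABP2 2.78-fold. The chemokine gene CXCL10 rose 3.04-fold, from 6.86 ± 0.021 to 8.46 ± 0.156. The complement gene C2 rose 2.29-fold, NDRG1, a gene induced by stress and hypoxia, 2.54-fold, and PLLP, which encodes the membrane protein plasmolipin, 2.69-fold. The metallothionein gene MT1H rose 4.33-fold, the aldo-keto reductase gene AKR1C1 2.43-fold and the alcohol dehydrogenase gene ADH1C from 4.11 ± 0.11 to 5.81 ± 0.355, and all of these have close paralogs whose transcripts the probes could share. The log2 difference of AKR1C1 was 1.28 for the probe used and ranged from 0.89 to 1.42 over the alternative settings. The other 3 genes that rose were KLKB1, from 4.11 ± 0.066 to 5.28 ± 0.169, and SULT2A1 and CFI, by factors of 2.01 and 1.99, and they were named after their values were seen. The control values of SULT1E1, ADH1C and KLKB1 lay near the lower quartile of all probes, which was 3.99 in control replicate 2, with no background level known, so no factor is given for them.

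**Figure D2:**
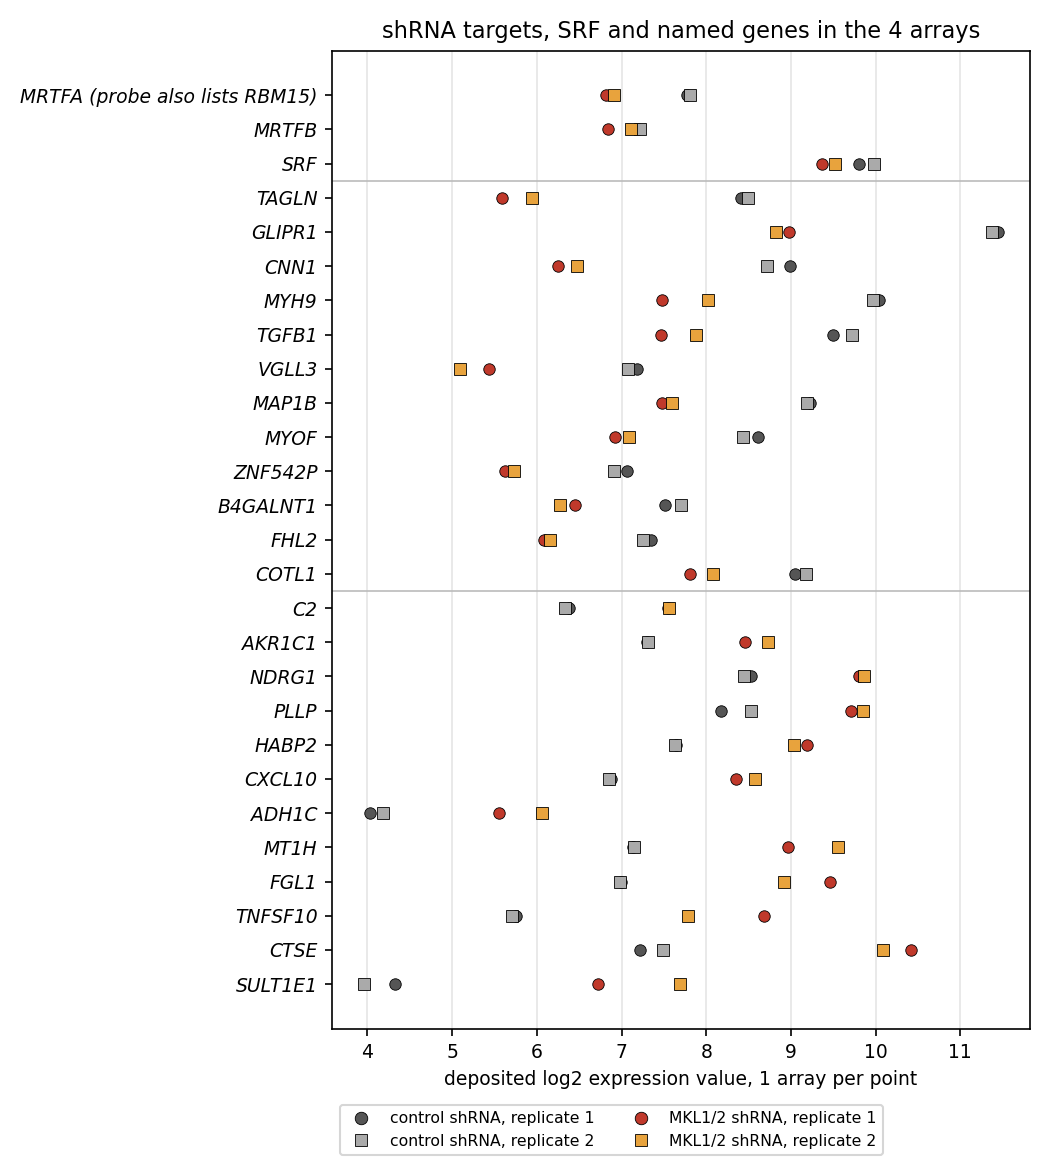
Deposited log2 expression values of the shRNA targets, SRF and the 24 named genes, with 1 point per array. For all 24 genes the 2 knockdown arrays lie on the same side of both control arrays, and the MRTFB values of knockdown replicate 2 (7.11) and the controls (7.20 and 7.22) lie close together.

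Genes known as targets of MKL and SRF, the MRTF-SRF targets, were lower as a group. Of 41 measured members, 6 fell over all genes tested (GLIPR1, TAGLN, CNN1, MYOF, MYH9 and FHL2) and none rose. Adjusted over the list alone, 26 fell and 2 rose. Those 2 were JUNB, an AP-1 subunit, and ITGA5, the fibronectin receptor subunit, with log2 differences of 0.35 (SE 0.095) and 0.43 (SE 0.151), named after their values were seen. ITGA5 lay at 9.13 in knockdown replicate 1 and 8.73 in replicate 2. The median log2 difference of the list was -0.54, and it was -0.63 in knockdown replicate 1 and -0.38 in replicate 2, against 0.055 between the controls. Limma's camera test, which compares a list with all other genes, called it lower (adjusted p = 2.80e-22), and the adjusted p was 0.366 with an estimated correlation between genes. MYOF was put on this list and on the YAP-TAZ list with knowledge of the study, so it is not independent evidence, and without it the camera adjusted p of the MRTF-SRF list was 5.02e-21. Serum-induced immediate early genes, which SRF controls together with ternary complex factors, were not called as a group. All 4 samples had 10% serum and the series compares no serum conditions, so the induction of these genes by serum was not tested. None of 24 measured members passed over all genes tested, and FOSL1, a Fos-family member, was the 1 that passed adjusted over the list alone, with a log2 difference of -0.50 (SE 0.092). DUSP1, a phosphatase of MAP kinases, lay at -0.56 (SE 0.175), with 8.56 in knockdown replicate 1 and 9.09 in replicate 2, MYC at 0.21 (SE 0.094) and KLF10 at 0.22 (SE 0.105). The median of that list was 0.03, its mean -0.01, and camera did not call it (adjusted p = 0.878).

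Other actin and adhesion genes and the targets of YAP and TAZ, co-activators of the Hippo pathway, were also lower as groups. Of 51 measured actin and adhesion genes outside the MRTF-SRF list, COTL1 fell over all genes tested, and 7 fell adjusted over the list alone. Among these 7, the actin bundling genes FSCN1 and LCP1 lay at -1.11 (SE 0.184) and -0.73 (SE 0.107), and ILK, the integrin-linked kinase, at -0.65 (SE 0.093). The list's median was -0.13 and camera called it lower (adjusted p = 1.25e-05), with an adjusted p = 0.427 with an estimated correlation. Of 27 measured YAP-TAZ targets, MYOF fell over all genes tested, and 6 fell and 2 rose adjusted over the list alone. CCN1 and CCN2, the matricellular genes formerly called CYR61 and CTGF, are on both the YAP-TAZ and the MRTF-SRF lists, and lay at -1.81 (SE 0.421) and -0.54 (SE 0.123). CCN1 depended on the array, at -2.53 without knockdown replicate 2 and -1.10 without knockdown replicate 1. IGFBP3, a binding protein of insulin-like growth factors, lay at -0.46 (SE 0.098). The YAP-TAZ median was -0.22 (camera adjusted p = 0.000406, and adjusted p = 0.62 with an estimated correlation). Without knockdown replicate 1 its median was -0.12 and the call was lost (adjusted p = 0.0637), and without MYOF its adjusted p was 0.00172.

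Camera called the lists of liver metabolic genes and of secreted plasma proteins higher, the latter not without knockdown replicate 1. Of 43 measured hepatocyte enzymes, transporters and liver transcription factors, none passed over all genes tested, and 8 rose and none fell adjusted over the list alone. Among the 8 were the urea cycle genes CPS1 (log2 difference 0.81, SE 0.095), ARG1 (0.77, SE 0.093) and OTC, and SLCO1B3, a bile acid and drug uptake transporter (1.18, SE 0.219). OTC read 3.25 ± 0.192 in control and 4.11 ± 0.293 in knockdown cells, near or below the lower quartile of all probes (3.99 in control replicate 2), so no difference is given for it. The list's median was 0.16, with 0.27 in knockdown replicate 1 and 0.11 in replicate 2, and camera called it higher (adjusted p = 3.48e-06, and adjusted p = 0.427 with an estimated correlation). Hepatocyte metabolism genes had a median of 0.089 without the dimmest 40% of genes (camera adjusted p = 0.0171). Of 48 measured plasma protein genes, none passed over all genes tested. Adjusted over the list alone 2 rose, namely HAMP, which encodes the iron hormone hepcidin (1.10, SE 0.182), and SERPIND1, which encodes heparin cofactor II (0.60, SE 0.109). ITIH1 and the complement gene CFB lay at 0.62 (SE 0.166) and 0.83 (SE 0.237), with 5.82 and 9.21 in knockdown replicate 1 and 5.36 and 8.45 in replicate 2. The plasma protein median was 0.081 (camera adjusted p = 0.0123, and adjusted p = 0.628 with an estimated correlation), but 0.018 without knockdown replicate 1, where the call was lost (adjusted p = 0.89).

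**Figure D3:**
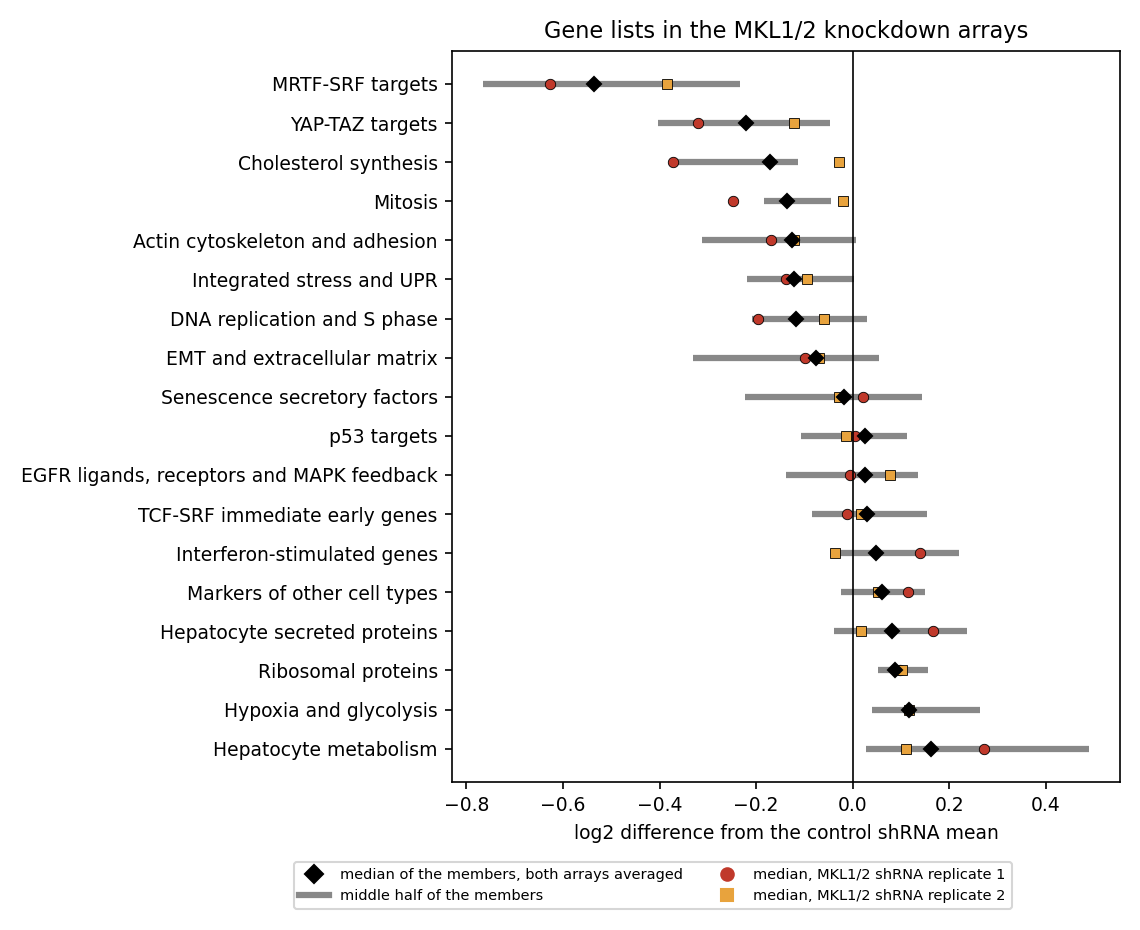
Median log2 difference from the control mean (horizontal axis) of the members of each of 18 gene lists, over both knockdown arrays (black) and in each of them (red and orange), with grey bars from the lower to the upper quartile of the members. The MRTF-SRF list lies lowest, at -0.54, and the hepatocyte metabolism list highest, at 0.16, and for mitosis (-0.25 and -0.021) and cholesterol synthesis (-0.37 and -0.028) replicate 1 lies far below replicate 2.

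Hypoxia and glycolysis genes and ribosomal protein genes shifted upwards by small amounts, alike in both knockdown arrays. NDRG1 was the member of the hypoxia and glycolysis list, of 34 measured, that rose over all genes tested and adjusted over the list alone. VEGFA, the angiogenic growth factor, lay at 0.35 (SE 0.099), the carbonic anhydrase gene CA12 at 0.40 (SE 0.114) and the lactate dehydrogenase gene LDHA at 0.35 (SE 0.102). The list's median was 0.12, at 0.117 in replicate 1 and 0.116 in replicate 2 (camera adjusted p = 0.000344, and adjusted p = 0.366 with an estimated correlation). None of 40 measured ribosomal protein genes passed over all genes tested or adjusted over the list alone. RPS25, RPL13, RPS7 and RPS29 lay between 0.26 for RPL13 and 0.30 for RPS25. The ribosomal median was 0.088 (camera adjusted p = 0.00205, and adjusted p = 0.366 with an estimated correlation).

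Mesenchymal and matrix genes went both ways, with more of them lower. Of 46 measured, TGFB1 fell over all genes tested, and 7 fell and 1 rose adjusted over the list alone. The collagen gene COL1A2 lay at -1.06 (SE 0.169), the collagen cross-linking enzyme LOX at -0.61 (SE 0.108) and the metalloprotease ADAMTS1 at -0.57 (SE 0.096). The 1 member higher adjusted over the list alone was SNAI1, a repressor of epithelial genes, at 0.81 (SE 0.168), named after its value was seen. The median was -0.076 (camera adjusted p = 0.00882, and adjusted p = 0.366 with an estimated correlation), and without knockdown replicate 1 the call was lost (adjusted p = 0.0822) at a similar median of -0.069.

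Camera called cell cycle, cholesterol synthesis and stress response lists lower, and these calls were lost without knockdown replicate 1. None of the 45 measured mitosis genes passed over all genes tested or adjusted over the list alone, and the mitotic kinase gene PLK1 lay at -0.52 (SE 0.094), BIRC5, which encodes survivin, at -0.31 (SE 0.117) and FOXM1, a transcription factor of mitotic genes, at -0.30 (SE 0.118). BIRC5 read 7.53 and FOXM1 9.71 in knockdown replicate 1, against 7.77 and 9.96 in replicate 2. The mitosis median was -0.25 in knockdown replicate 1 and -0.021 in replicate 2 (camera adjusted p = 0.000476 with both, 0.944 without replicate 1, and adjusted p = 0.628 with an estimated correlation). None of the 44 measured DNA replication genes passed by either adjustment, and ORC1 and MCM10, which act at replication origins, both lay at -0.42 (SE 0.108 and 0.131). Their list's median was -0.20 in replicate 1 and -0.06 in replicate 2 (camera adjusted p = 0.00137 with both, 0.463 without replicate 1, and adjusted p = 0.62 with an estimated correlation). Of 19 measured cholesterol synthesis genes none passed over all genes tested, and CYP51A1, lanosterol demethylase, was the 1 that fell adjusted over the list alone, at -0.54 (SE 0.097). Its list lay at -0.37 in replicate 1 and -0.028 in replicate 2 (camera adjusted p = 0.000492 with both, 0.463 without replicate 1, and adjusted p = 0.62 with an estimated correlation). In the list of the integrated stress and unfolded protein response, none of 35 genes passed over all genes tested. The cystine transporter SLC7A11 and the mitochondrial folate enzyme ALDH1L2 fell adjusted over the list alone, at -0.93 (SE 0.128) and -0.66 (SE 0.105). ASNS, asparagine synthetase, lay at -0.45 (SE 0.113), whereas EDEM1 went the other way, at 0.32 (SE 0.094). Of the 35 genes, 26 were lower and 9 higher. The stress list's median was -0.12, at -0.14 in replicate 1 and -0.094 in replicate 2 (camera adjusted p = 0.00772, 0.232 without knockdown replicate 1, and adjusted p = 0.62 with an estimated correlation).

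Camera did not call the lists of senescence, p53, interferon and EGFR signalling genes with all 4 arrays. None of 39 measured secreted senescence factors passed over all genes tested, and 2 rose and 2 fell adjusted over the list alone. The urokinase gene PLAU and the EGFR ligand EREG lay at 0.81 (SE 0.106) and 0.73 (SE 0.114), and IGFBP4 and IGFBP3 at -0.53 (SE 0.11) and -0.46 (SE 0.098). The senescence list's median was -0.018 (camera adjusted p = 0.681), at 0.021 in knockdown replicate 1 and -0.028 in replicate 2. Senescence secretory factors had a median of -0.19 without the dimmest 40% of genes, also without a call (camera adjusted p = 0.225), while limma's fry test of changes in either direction, which 11 of the 18 lists passed, gave an adjusted p of 4.50e-05. Of 27 measured p53 targets none passed over all genes tested. CDKN1A, the cyclin-dependent kinase inhibitor p21, lay at 0.43 (SE 0.171) and at 6.99 in knockdown replicate 1 against 6.48 in replicate 2, while SESN1 lay at 0.46 (SE 0.135). The stress cytokine GDF15, the 1 p53 target that fell adjusted over the list alone, lay at -0.64 (SE 0.113), and TP53I3 at -0.40 (SE 0.092). The p53 median was 0.025 and its mean 0.011, whereas camera gave the opposite sign without a call (adjusted p = 0.972). None of 38 measured interferon-stimulated genes passed over all genes tested. IFITM3 and IFIT3 lay at 1.10 (SE 0.182) and 0.51 (SE 0.111), and RIGI and SAMD9 at -0.63 (SE 0.135) and -0.44 (SE 0.099), and these 4 passed adjusted over the list alone. The interferon median was 0.048 (camera adjusted p = 0.131), 0.14 in knockdown replicate 1 and -0.037 in replicate 2, and the list passed camera without knockdown replicate 2 (adjusted p = 0.00695) and without control replicate 2 (adjusted p = 0.0443). Of 28 measured genes of EGFR signalling none passed over all genes tested, EREG was the 1 that rose adjusted over the list alone, ERBB2 lay at -0.35 (SE 0.105) and the adaptor SHC1 at -0.40 (SE 0.101), and camera did not call the list (adjusted p = 0.726). Of 27 measured markers of fibroblasts, endothelium, leukocytes and HEK293-type cells, none passed over all genes tested, with NES at -0.72 (SE 0.115) and FCER1G at 0.61 (SE 0.125) passing adjusted over the list alone (camera adjusted p = 0.265).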

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

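The signs of the 32 called genes held under every alternative in which they were tested, but their number did not. The groups of each called gene did not overlap, so leaving out 1 array could not turn a sign. Settings that changed only the variance model, the block or the set of genes or probes tested left the differences as they were. Only renormalizing or averaging probes could have turned a sign. Counts of lower and higher genes (17 and 15) became 27 lower without the dimmest 40% of genes, 27 lower after quantile normalization, 28 and 23 with robust eBayes, 4 and 1 at an adjusted p under 0.01, and 78 and 66 at an adjusted p under 0.1. With all 33297 probes tested, 0 and 0 passed in limma (smallest adjusted p 0.105, 3486 at an unadjusted p under 0.05), where the prior degrees of freedom fell from 4.12 to 2.87. Without variance moderation 0 and 0 passed (smallest adjusted p 0.194, 1840 at an unadjusted p under 0.05). Leaving out each array in turn gave 0 to 442 lower and 0 to 339 higher genes. Without a control array the spread comes from the 2 knockdown arrays alone, and without a knockdown array from the 2 control arrays alone, with the lone array assumed to vary like the others. With the replicate block 38 and 55 genes passed, including all 32. The samples share only a number, with a correlation of -0.067 across genes between the deviations of same-numbered arrays, and the block changed no call of the MRTFA probe, MRTFB or the gene lists. The MRTFA probe stayed at -0.93 but lost its call with all probes (adjusted p = 0.199) and without moderation (adjusted p = 0.416), and ranged from -0.975 to -0.881 when each array was left out, with adjusted p between 0.0145 and 0.732. MRTFB was not called under any of these. Of the 18 lists, 8 were called lower and 4 higher; with an estimated correlation it was 0 and 0, with fry 0 and 0 (smallest adjusted p 0.0655, 5 lists at an unadjusted p under 0.05), and leaving out each array gave 2 to 8 lower and 3 to 5 higher. Without the dimmest genes the lists named integrated stress and unfolded protein response and EMT and extracellular matrix lost their calls (adjusted p = 0.0513 each). Lists that were not called changed sign in the test at times. The immediate early list turned with fry (median 0.03) and when an array was left out (medians from -0.011 to 0.055). The p53 list turned without the dimmest genes (median 0.024), after quantile normalization (0.03), with the block (0.025) and when an array was left out (-0.018 to 0.021). The interferon and EGFR lists turned when an array was left out, with medians from -0.037 to 0.14 and from -0.005 to 0.077. The cause was not tested for any of these. Over 87 named genes and 1120 results under alternatives, 976 kept direction and side of the threshold, 96 lost the call, 48 gained it and 0 reversed. A reversal could not occur where only the variance model changed or 1 array was left out, since these genes' groups did not overlap. Testing lists without MYOF was chosen after seeing the data. Background levels are unknown. The simulation did not count how often single genes changed by less than 2-fold, as MRTFB was here, were called, so that rate is not known.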

Other observations

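The gene families below, defined by symbol, and their tests were chosen after the values were seen, as was the use of every test but the share kept after quantile normalization to weigh an explanation, although leaving out arrays or dim genes, the estimated correlation and the fit of all probes were planned as settings. Of 13 measured metallothionein genes and pseudogenes, 11 were higher in both knockdown arrays than in both controls, and the family had a median log2 difference of 0.76 (camera adjusted p = 3.93e-08 over 10 families, and adjusted p = 0.215 with an estimated correlation). MT1H rose (2.11, limma adjusted p = 0.0284), MT1G read 11.82 in knockdown replicate 1 and 12.56 in replicate 2 against 11.10 ± 0.144 in the controls, MT1M read 9.10 in knockdown replicate 1 and 11.00 in replicate 2 against 8.05 ± 0.197 in the controls, and the family's median was 0.39 in knockdown replicate 1 and 1.12 in replicate 2. MT1E and MT1X overlapped between the groups, and in knockdown replicate 1 both lay below both controls, at 9.05 against 9.30 and 9.33 for MT1E and at 9.99 against 10.86 and 11.05 for MT1X. These genes are close paralogs, so they are not independent measurements. The groups did not overlap for 7 of 9 aldo-keto reductases, all of these higher, and the family had a median of 0.48 (camera adjusted p = 2.45e-05, and adjusted p = 0.215 with an estimated correlation). Of these 9, AKR1C3, AKR1C4 and AKR1C6P had control means below the lower quartile of all probes (3.99 in control replicate 2). AKR1C8 turned from 0.018 to -0.005 after quantile normalization. Beside the called AKR1C1, AKR1B10 read 8.41 in knockdown replicate 1 and 7.28 in replicate 2 against 5.55 ± 0.105 in the controls, and AKR1C2 8.18 and 6.78 against 5.87 ± 0.037. Of 5 UDP-glucuronosyltransferases 2B, UGT2B7, UGT2B10, UGT2B17 and UGT2B28 had control means between 1.88 and 3.49, below that quartile, so no family value is given. UGT2B4 read 8.05 and 6.87 in knockdown replicates 1 and 2 against 5.74 ± 0.216. Of 24 complement genes, 10 were higher with no overlap between the groups and 14 overlapped, and the median was 0.26, at 0.38 in knockdown replicate 1 and 0.14 in replicate 2 (camera adjusted p = 7.16e-07, and adjusted p = 0.215 with an estimated correlation). C2 and CFI rose, while C1R read 6.97 in knockdown replicate 1 and 6.41 in replicate 2 against 5.94 ± 0.088 in the controls, and the lectin gene MBL2 8.19 and 6.66 against 5.60 ± 0.005.

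Among smaller families, sulfotransferases went both ways, with SULT1E1 and SULT2A1 higher past the threshold and SULT1C4 at -0.64 (median 0.098, 0.166 in knockdown replicate 1 and 0.03 in replicate 2, camera adjusted p = 0.0134, and adjusted p = 0.215 with an estimated correlation). Of these, SULT1B1, SULT1C3 and SULT6B1 had control means below the lower quartile of all probes (3.99 in control replicate 2). Of 7 alcohol dehydrogenases, ADH1C rose, while its paralog ADH1A overlapped between the groups, at 5.06 in knockdown replicate 1 and 5.86 in replicate 2 against 5.21 ± 0.035 in the controls (family median 0.133, camera adjusted p = 0.0265, 0.13 without knockdown replicate 2 at a median of 0.039, and adjusted p = 0.215 with an estimated correlation). The alcohol dehydrogenase genes ADH1B, ADH4 and ADH7 also had control means below that lower quartile. Of 12 microtubule-associated proteins and stathmins, MAP1B fell and MAP1A lay at -0.93, while the family's median was -0.007 and camera did not call it (adjusted p = 0.266). Tropomyosins, calponins and myosin light chains had a median of 0.005, and of -0.022 after quantile normalization, although camera called them lower, with CNN1 at -2.49 and MYL9 at -1.24 while the groups overlapped for TPM1. The PDZ and LIM domain family had a median of -0.058, with PDLIM3 at -0.95, while the groups overlapped for PDLIM1. For these families camera gave adjusted p of 0.0312 and 0.046, and adjusted p = 0.215 for each with an estimated correlation. Without knockdown replicate 1 neither was called (adjusted p = 0.092 and 0.063), nor was the PDZ and LIM domain family without knockdown replicate 2 (0.112) or control replicate 2 (0.0589). The 176 small nucleolar RNAs were not called (median -0.003, and 0.003 after quantile normalization, camera adjusted p = 0.397). Neither the 12083 unlisted probes nor the 1754 that list several genes held a probe past an adjusted p of 0.05 in limma when all probes were tested together, a fit in which 0 of all probes passed and 3486 had an unadjusted p under 0.05. The other 2 ways of splitting the 4 arrays into pairs gave 0 called genes each, with 218 and 327 genes at an unadjusted p under 0.05 against 2632 for the real split. In each of those other 2 splits a group held 1 control and 1 knockdown array. The knockdown difference therefore entered the spread, so these counts do not show what chance would give. The 3 splits are too few for a share under 0.05.

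The mitosis, DNA replication and cholesterol synthesis lists were lower mainly in knockdown replicate 1. That array has a narrower spread of values, which may have contributed. After quantile normalization, which gives the arrays one distribution, the medians in replicate 1 were -0.20 for mitosis, -0.14 for DNA replication and -0.33 for cholesterol synthesis, all below the central 95% of random lists matched on level (lower bounds -0.099, -0.101 and -0.135), so the spread is argued against as the whole cause, but a part stays open because the share kept was 0.796, 0.72 and 0.877. A weaker knockdown in replicate 2 is another candidate explanation and cannot be told apart: the MRTFA probe fell nearly as far there (ratio 0.90), but the MRTF-SRF median fell less (ratio 0.61), and MRTFB, not called, lay at -0.365 in replicate 1 and -0.095 in replicate 2. No group of the design separates the replicates, so no biological explanation was tested.

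The hepatocyte metabolism list was higher in both knockdown arrays. An upward drift of dim probes is argued against, since the list's median of 0.16 lay above the central 95% of matched random lists (-0.038 to 0.071). Hepatocyte metabolism genes had a lower median of 0.089 without the dimmest 40% of genes, where the list was still called (camera adjusted p = 0.0171), and an effect of knockdown replicate 1 alone is argued against too, since the list was called without it (adjusted p = 0.000436). That correlated genes of one programme were counted as independent stays open, with an adjusted p of 0.427 with an estimated correlation from 2 residual degrees of freedom. An effect of the knockdown itself was not separated from other differences between the infected populations, and the hepatocyte secreted list lost its call without knockdown replicate 1 (median 0.018, adjusted p = 0.89).

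CXCL10 and TNFSF10 can be induced by interferon, so a general type I interferon response was a candidate explanation for their rise. The control cells also carried an shRNA vector, so a response common to both vectors would not appear as a difference. The upper quartile of the 38 interferon-stimulated genes was 0.22, below a bound of 0.80 set from the log2 rise of CXCL10 after the values were seen. Of the 38 genes, 23 were higher and 15 lower, with RIGI and SAMD9 among the lower. These values argue against a rise of most of the list by 0.80 or more. The bound does not cover a weaker general response, so that stays open. A narrower response stays open too, with IFITM3 at 1.10, as does an effect of the knockdown itself, which the design confounds with the hairpin sequences used.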
